A study of Mus musculus with 6 samples.

How the data were processed

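Gene expression was measured on 6 Affymetrix arrays hybridised with biotin-labelled cDNA made from total RNA of primary mouse brain cultures. Neural cells were taken from OF1 embryos at embryonic day 17 and allowed to differentiate in fetal calf serum into a mixed culture of neurons and glia. Serum-free cultures then received 1,25-dihydroxyvitamin D3, the hormonally active form of vitamin D (1,25D), at 10 nM or vehicle. The duration of treatment is not given in the sources used here. Each group held 3 arrays, which the labels call biological replicates. Nothing in the labels says whether equal replicate numbers mark a shared litter, day or culture, so the p-values measure the spread between these samples.

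The deposited values are intensities per transcript cluster, normalised and summarised by the authors with RMA in Affymetrix Expression Console, per the submitters' processing notes. The versions, the probe set level and any filter are not given in the sources used here. The deposited intensity values are on a linear scale, as the file itself shows, with a lowest value of 8.05 and a highest of 22019 over the 6 arrays, so log2 was taken before any test. RMA gives no detection call, so it cannot be said from these values which genes were above background, and differences of dim genes are compressed. For arrays the number of replicates, not a read depth, limits the precision. No column of the table belonged to another sample.

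The table held 35556 rows. GEO's platform annotation paired 21789 of them with 1 gene symbol, 1621 with several symbols, and left 12146 unnamed here. The rows with 1 symbol stood for 19938 genes. For the 999 genes with several rows, the row with the highest mean over the 6 arrays was used. Genes are named as in that annotation, and older list symbols were updated through RefSeq synonyms. Of the genes in the lists below, 50 had no row with a single symbol and are not analysed here, and for the same reason 1 planned check was not run. No coordinates are given, since no genome build is named for the values.

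The comparison was 1,25D minus control with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes without a trend), with no fold minimum and no filter on dim genes. Adjusted p is Benjamini-Hochberg over the 19938 genes, with a threshold of 0.05. Before the data were examined, 27 gene lists with 499 distinct genes were fixed, 449 of which were measured. The lists covered vitamin D action, the cell types such a culture could hold, and signalling and stress programmes. Each list was tested with camera at a preset correlation of 0.01 between genes and adjusted over the 27 lists. Camera with a correlation estimated per list, and fry, stood beside it. The rule for naming genes, also fixed then, took the called genes with the largest rise or fall and non-overlapping groups. With fewer than 10 calls it added the 5 smallest p-values in each direction, given as values. In each list it took up to 4 called members, or the 2 smallest p-values where none passed, and it always took a short set of receptor, marker and neurotrophic genes. The genes called only with the replicate block, other list members and all lists described as added were chosen after their values were seen.

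Equal replicate numbers were checked for pairing through the correlation of deviations from the group means across genes. The correlation was 0.51, 0.65 and 0.46 for the pairs numbered 1, 2 and 3, against values between -0.51 and -0.012 for unequal numbers. Deviations in a group sum to 0 for each gene, so positive values for equal numbers force negative ones elsewhere. The values for unequal numbers are thus no independent reference. On the positive values the numbers were treated as pairs, a hint from the data and not from the labels. With 3 unpaired arrays against 3, the smallest two-sided p an exact permutation test of a single gene can give is 0.1. For pairs it is higher, since only 4 of the 10 splits of the arrays part all pairs. Calls thus rest on the variance model shared across genes. The fit without the block was fixed as the reported one, and the fit with the replicate number as a block (3 pairs) stands beside it where it moved a count by more than 1.5 times or changed the call of a gene or of a list fixed in advance.

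Both fits were run on simulated data for the 19938 genes, with residual variances drawn from the distribution estimated by limma's blocked fit. The variance model on which the calls rest thus held by construction, so the simulation does not test it. Each gene was drawn independently of the others, with an effect of the replicate number built in, a setting that favours the blocked fit. A change of 1 on the log2 scale was recovered for 61.2% of genes without the block and 94.0% with it. A change of 0.5 was recovered for 5.97% and 26.9%, and a change of 2 for 97.0% and 100%. False calls numbered 2 without and 9 with the block. In simulated lists of 20 genes, a shift of 0.3 was called by camera at the preset correlation in both fits, and at an estimated correlation only without the block (adjusted p = 0.29 with it). By fry the shifted list had an adjusted p of 6.2e-04 without the block and 0.064 with it. Members of these simulated lists were uncorrelated by construction, whereas the estimate was 0.75 for cholesterol synthesis and 0.28 for proliferation. For interferon response and for unfolded protein and amino acid stress it was -0.066 and 0.007, near the simulated setting. The simulation therefore does not show how camera at the preset correlation behaves where members vary together. The other settings fixed in advance were quantile normalisation, median centring, 2 filters on dim genes, a trended robust variance model, array weights, other choices of rows, a fold minimum of 1.5, an unmoderated test, the replicate block and the omission of each array.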

Results

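The series compared mixed neuron-glial cultures of embryonic mouse brain exposed to 1,25-dihydroxyvitamin D3 with vehicle-treated cultures, to find genes that the hormone induces. There were 3 control arrays and 3 arrays of cultures treated at 10 nM, and 19938 genes could be named and tested. The median intensity over genes lay between 240.4 and 252.9 on the 6 arrays, and the median log2 difference over all genes was 0.0074. Arrays with the same replicate number resembled each other beyond their group, so the counts of called genes are given without and with the pairs as a block.

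In the treated cultures 5 genes rose and none fell (limma, adjusted p under 0.05). Grpr, the receptor for gastrin-releasing peptide, had the largest rise, from a log2 intensity of 6.50 ± 0.26 to 9.74 ± 0.31 (SD, n = 3 each), a 9.42-fold increase with an adjusted p of 0.0041. Crabp1, a cytosolic binding protein for retinoic acid, rose 6.31-fold, from 9.49 ± 0.32 to 12.15 ± 0.44 (adjusted p = 0.029). S100g, the calcium-binding protein calbindin-D9k and a known target of the vitamin D receptor, rose 2.95-fold with a log2 difference of 1.56 ± 0.13 (SE, adjusted p = 0.022). Fbln1, which encodes the matrix glycoprotein fibulin-1, rose 2.20-fold with a log2 difference of 1.14 ± 0.10 (SE, adjusted p = 0.022). Lcn8, a lipocalin, rose 1.99-fold with a log2 difference of 0.99 ± 0.10 (SE, adjusted p = 0.042). Each of the 5 was higher in all 3 treated arrays than in any control. At an unadjusted p under 0.05 there were 295 genes (1.48%, 190 of them higher) without the block and 1152 (5.78%, 631 of them higher) with it, where chance gives 5%. The median SE over genes was 0.124 without the block and 0.086 with it. Without the block, differences between replicate numbers count as error, which raises the p-values if the numbers mark pairs. The groups did not overlap for 828 genes, 4.15% of those tested; chance gives 10% for 3 arrays against 3 that are not paired, so that share is no reference for these pairs. Crabp1 and Lcn8 lost their call after quantile normalisation (adjusted p = 0.051 and 0.056), and Lcn8 also after median centring (0.052) and in the test over every row with 1 gene symbol. Quantile normalisation left the log2 difference of Crabp1 at 2.67, against 2.66 as reported. That of Lcn8 was 0.97 after quantile normalisation and 0.98 after median centring, against 0.99. No gene was called by limma over all rows of the table, named or not (521 rows at an unadjusted p under 0.05), or by the test without moderation of the variance (339 genes), which leave each log2 difference as it was and change its error or adjustment. With 1 array left out, the count was 0 without control replicate 3 and 0 without 1,25D replicate 3, 1 without 1,25D replicate 1, and 2 without control replicate 1, control replicate 2 or 1,25D replicate 2. Grpr was called in each of the 4 settings that gave any gene. The log2 differences moved little over the 6 omissions, between 3.09 and 3.40 for Grpr, 2.46 and 2.89 for Crabp1, 1.49 and 1.67 for S100g, 1.11 and 1.19 for Fbln1, and 0.95 and 1.05 for Lcn8, so the lost calls show no array that carried these rises.

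**Figure D1:**
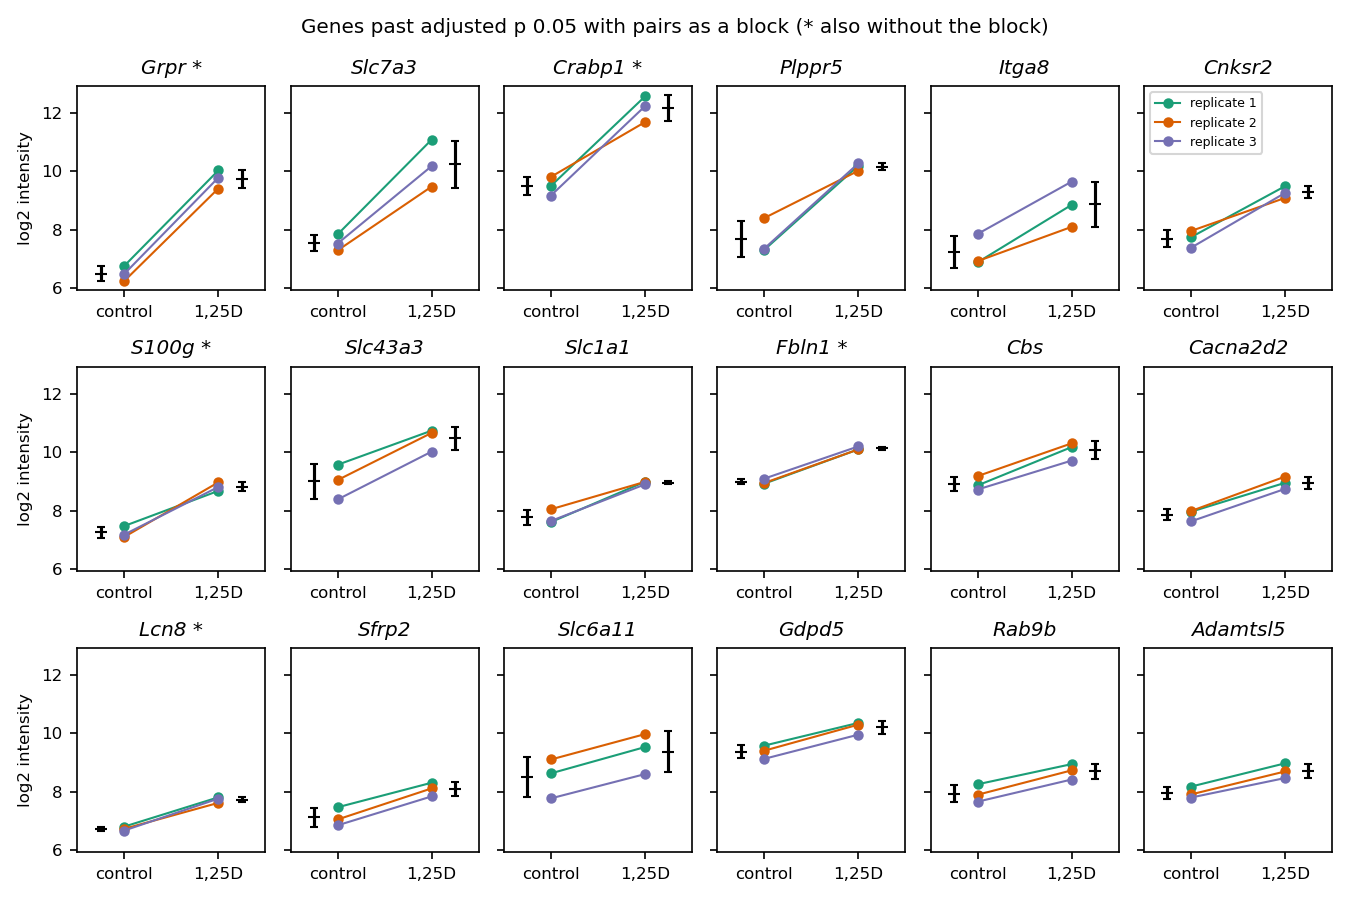
Log2 intensity of the 18 genes past an adjusted p of 0.05 with the pairs as a block, in control and 1,25D cultures. Points are arrays, coloured lines join arrays of one replicate number, black bars are the mean ± SD of 3 arrays, and an asterisk marks the 5 genes also past the threshold without the block. Every line rises from control to 1,25D.

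With the pairs as a block, 18 genes rose and none fell, and the 5 genes above were all among them. The other 13 had adjusted p-values between 0.058 and 1.00 without the block, and their names were chosen after the values were seen. Slc7a3, a cationic amino acid transporter, rose 6.44-fold with the block, from 7.55 ± 0.27 to 10.24 ± 0.80 (SD, n = 3 each, adjusted p = 0.022). Slc43a3 rose 2.77-fold (adjusted p = 0.024), Slc1a1, a glutamate transporter of neurons, rose 2.28-fold (adjusted p = 0.024), and Slc6a11, a GABA transporter, rose 1.82-fold (adjusted p = 0.024). Slc6a11 was the single gene of the 18 whose groups overlapped. Its difference was 0.90, 0.87 and 0.83 in pairs 1, 2 and 3, while its level differed between replicate numbers, with an SD of 0.67 among the controls. Plppr5, a phospholipid phosphatase-related membrane protein, rose 5.52-fold (adjusted p = 0.044), Cnksr2, a scaffold of Ras signalling at synapses, rose 2.99-fold (adjusted p = 0.029), and Cacna2d2, an auxiliary subunit of voltage-gated calcium channels, rose 2.13-fold (adjusted p = 0.024). Itga8, an integrin chain, rose 3.12-fold, Sfrp2, a secreted modulator of Wnt signalling, rose 1.95-fold, and Cbs, which makes cystathionine from homocysteine, rose 2.20-fold, with adjusted p-values of 0.029, 0.024 and 0.024. Gdpd5 rose 1.78-fold, Rab9b 1.69-fold and Adamtsl5 1.68-fold, with adjusted p-values of 0.029, 0.045 and 0.046. The blocked count was 10 after quantile normalisation, 40 with array weights, 1 over all rows of the table (Grpr) and 0 without moderation (1015 genes at an unadjusted p under 0.05). It was 40 without replicate 1 (38 higher, 2 lower), 3 without replicate 2 (Crabp1, Grpr and Plppr5) and 45 without replicate 3 (40 higher, 5 lower), each from 2 pairs.

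**Figure D2:**
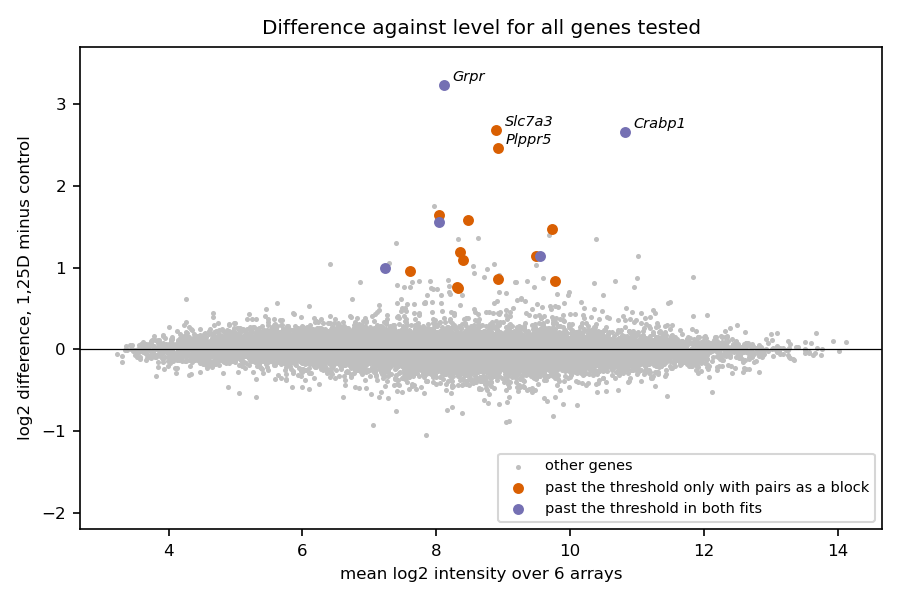
Log2 difference, 1,25D minus control, against the mean log2 intensity over the 6 arrays for the 19938 genes tested. Purple points are the 5 genes past the threshold in both fits and orange points the 13 past it only with the pairs as a block. All 18 lie above 0.

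No gene fell past the threshold in either fit. The 5 genes with the smallest unadjusted p among those with lower means were Cpxm2, Morc4, Casp12, Chrna4 and Cmbl. The lowest adjusted p among them was that of Cpxm2, a carboxypeptidase-like protein, at 0.62 without the block and 0.14 with it, for a log2 difference of -0.66 ± 0.12 (SE). Casp12, an inflammatory caspase family member, had a log2 difference of -0.65 ± 0.14, Cmbl of -0.63 ± 0.16, Morc4 of -0.46 ± 0.09, and Chrna4, a nicotinic acetylcholine receptor subunit, of -0.40 ± 0.10 (SE). By pair, counted after the data were seen, in each of the 3 pairs 39 genes were at least 1.5-fold higher and 0 were at least 1.5-fold lower, and 11 genes were at least 2-fold higher in each pair. With the labels of 1 pair swapped, the count at 1.5-fold was 0 higher and 1 lower for pair 1, 0 and 0 for pair 2, and 1 higher and 14 lower for pair 3.

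Among the measured genes of vitamin D reception and metabolism, 0 of 13 passed over all genes. Vdr, the vitamin D receptor itself, had a 3.39-fold higher mean in treated cultures, 8.85 ± 0.67 against 7.10 ± 0.16 (SD, n = 3 each), with an adjusted p of 0.38 without the block and 0.052 with it. In the blocked fit it passed with array weights (0.017), without the genes of identical replicate 1 values (0.048), without replicate 1 (5.5e-04) and without replicate 3 (0.030), and not in the other settings, where the highest adjusted p was 0.72 (without replicate 2). Without replicate 2 its log2 difference was 1.85, against 1.76 over all pairs. Its difference was 2.38, 1.58 and 1.32 in the 3 pairs. Each fit without a replicate holds 2 pairs, so its adjusted p rests on the likeness of 2 differences and on the shared variance model. Adjusted over the list alone, 1 gene passed without the block (Vdr) and 2 with it (Vdr and Rxrg, a retinoid X receptor). Cyp27b1, the enzyme that makes 1,25-dihydroxyvitamin D3, had a log2 difference of 0.01 ± 0.09, Rxra, a heterodimer partner of the receptor, of 0.13 ± 0.17, and Lrp2, an endocytic receptor for the vitamin D carrier, of -0.13 ± 0.13 (SE). Cyp27b1 was dim and among the genes of identical replicate 1 values (6.51 in both arrays), which fixes its pair 1 difference at 0. Of 33 measured genes known as receptor targets in other tissues, 1 rose (S100g) and 32 did not pass, in either fit. Over all 19938 genes, 5 passed without the block and 18 with it. Some targets were dim, such as Cyp3a11, Trem1 and Tph2 with control means of 4.67, 5.84 and 5.89, so their small differences say little. Gadd45a had a log2 difference of 1.04 ± 0.46 (SE) and did not pass. Adjusted over the list alone, 2 passed in both fits, S100g and Atp2b1, a plasma membrane calcium pump with a log2 difference of 0.76. Neither list was called as shifted in 1 direction (camera, adjusted p = 0.74 and 0.26).

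In the list of retinoid signalling, Crabp1 rose and 13 of 14 members did not pass over all genes. Adjusted over the list alone, Crabp1 and Tgm2, transglutaminase 2, passed in both fits. With the block, Rarb, a retinoic acid receptor, and Aldh1a1, which makes retinoic acid, passed as lower, with log2 differences of -0.42 and -0.67. The list had a median difference of 0.02 and a camera adjusted p of 0.50. None of the 18 measured neurotrophic factors and receptors passed over all genes. Gfra1, the co-receptor for GDNF, passed adjusted over the list alone in both fits, with a 1.48-fold higher mean and a log2 difference of 0.57 ± 0.12 (SE). The log2 difference was 0.45 ± 0.32 for Vegfa, 0.05 ± 0.12 for Gdnf, 0.05 ± 0.10 for Bdnf and -0.21 ± 0.11 for Fgf2 (SE). The camera adjusted p of this list was 0.68. Among 21 measured genes associated with neurodegenerative disease none passed, and App, the amyloid precursor protein, had a log2 difference of 0.00 ± 0.10 (SE, camera adjusted p of the list 0.94).

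Across 9 lists with 119 measured markers, 0 rose and 0 fell in either fit, the list medians lay between -0.05 and 0.06, and the camera adjusted p-values between 0.26 and 0.88. Some markers were bright, such as Gfap and Map2 with control means of 11.61 and 10.94. Others, such as Aif1 at 6.03 and Nefl at 5.99, lay below the lower quartile of genes, which was 6.69 to 6.86 on the 6 arrays. Differences of such dim markers are compressed, so their small size says little about cell content. Astrocyte markers had a median of -0.05 (14 genes, adjusted p = 0.35), with Gfap at -0.08 ± 0.31 and Aldh1l1 at -0.27 ± 0.15 (SE). Neuron markers had a median of 0.00 (20 genes, adjusted p = 0.85), with Tubb3 at -0.05 ± 0.29, Map2 at -0.29 ± 0.25 and Rbfox3 at -0.34 ± 0.14 (SE). Oligodendrocyte lineage markers had a median of -0.05 (15 genes, adjusted p = 0.64, Mbp at 0.09 ± 0.15) and microglia and macrophage markers of 0.05 (17 genes, adjusted p = 0.26, Aif1 at 0.12 ± 0.10). The medians were 0.06 for endothelial markers, -0.01 for pericyte markers, 0.02 for meningeal fibroblast markers, 0.04 for the 4 red blood cell markers and -0.02 for neural progenitor markers, with adjusted p-values of 0.68, 0.87, 0.38, 0.85 and 0.88. Median and mean differed in sign for neuron markers (mean -0.02), pericyte markers (mean 0.03) and neural progenitor markers (mean 0.03). Adjusted over the list alone, Pdgfrb, a receptor of pericytes, was the single marker that passed, with the block (1.40-fold). Without control replicate 3 or without 1,25D replicate 2 the astrocyte list was called lower (adjusted p = 0.0034 and 0.0020), and without 1,25D replicate 1 the neuron list was called higher (adjusted p = 0.035), all at the preset correlation. With an estimated correlation in the same omissions, the astrocyte list had an adjusted p = 0.88 and 0.91 and the neuron list an adjusted p = 0.60. Genes of ciliated ependymal cells, a list added after the data were seen, differed between arrays, with a median difference of -0.85, -0.37 and 0.47 in pairs 1, 2 and 3.

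**Figure D3:**
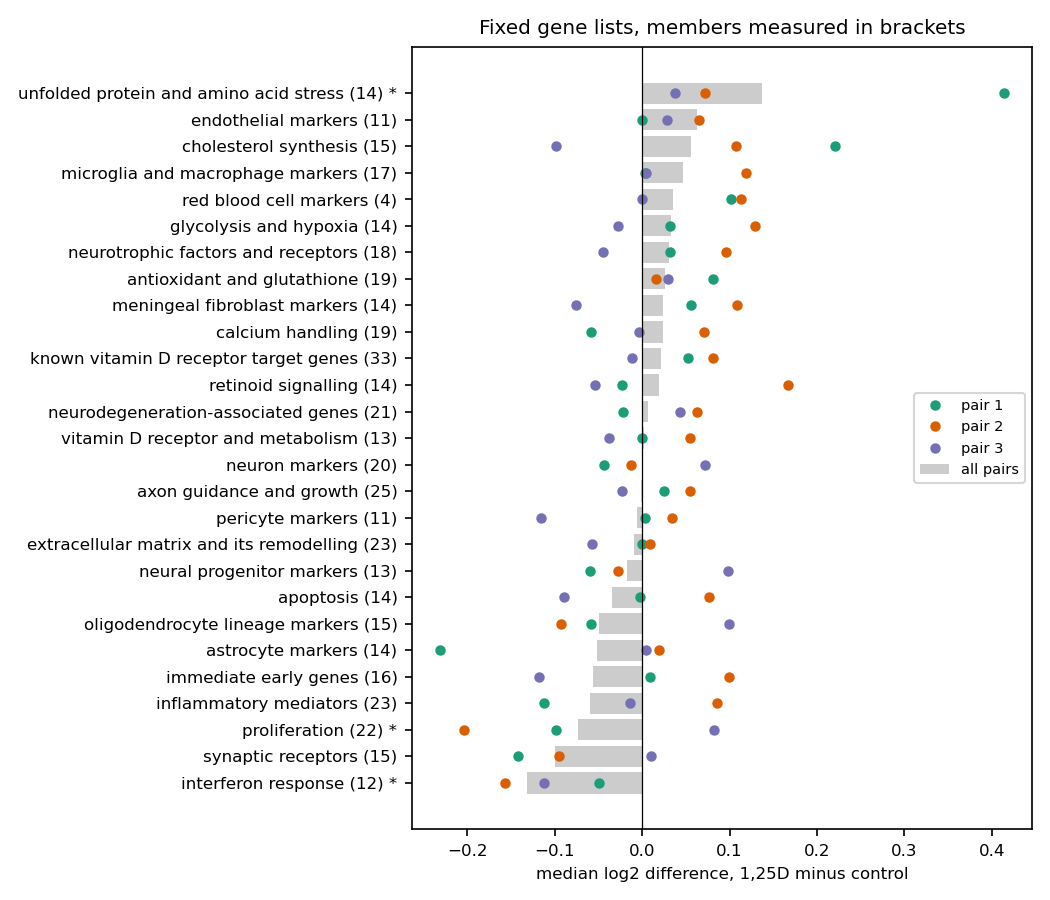
Median log2 difference, 1,25D minus control, over the measured members of each of the 27 gene lists fixed in advance. Grey bars are medians of the differences between group means, coloured points the medians in each pair, and asterisks mark the 3 lists past an adjusted p of 0.05 with camera at the preset correlation; pair 3 lies on the other side of 0 from pairs 1 and 2 for proliferation.

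At the preset correlation, camera called 3 of the 27 lists, in which no single member passed over all genes or adjusted over the list alone. The interferon response list was lower, with 10 of its 12 members below 0, a median of -0.13 and an adjusted p of 0.0030 (0.0073 with the block). This call was lost with an estimated correlation (adjusted p = 0.41 with an estimated correlation, and 0.89 with the block added) and with fry (0.093, and 0.27 with the block). The list's estimated correlation was -0.066 without the block, below the preset 0.01, so correlation between members did not cost it that call. With the block, both camera at an estimated correlation and fry missed a simulated shift of 0.3. The blocked values of 0.89 and 0.27 are thus no evidence against a shift. Usp18, an interferon-induced protease, had a log2 difference of -0.41 ± 0.21 and Ifit1 of -0.22 ± 0.11 (SE). The list of unfolded protein and amino acid stress was higher, with 11 of 14 members above 0, a median of 0.14 and an adjusted p of 0.020 (0.021 with the block). It had an adjusted p = 0.43 with an estimated correlation and 0.71 with fry (0.89 and 0.81 with the block). Its estimated correlation was 0.007 without the block, also below the preset value. Hspa1a, an inducible heat shock protein, had a log2 difference of 0.37 ± 0.14 and Herpud1 of 0.30 ± 0.14 (SE), and the list median was 0.41 in pair 1 against 0.07 and 0.04 in pairs 2 and 3. The proliferation list was lower, with a median of -0.07 over 22 members and an adjusted p of 0.042 (0.021 with the block). It had an adjusted p = 0.92 with an estimated correlation and 0.96 with fry (0.89 and 0.81 with the block), 0.16 after quantile normalisation and 0.12 without the lowest 25% of genes. Kif11, a mitotic kinesin, had a log2 difference of -0.25 ± 0.17 and Mcm4, a replication helicase subunit, of -0.15 ± 0.10 (SE). The stress call was lost without control replicate 1, control replicate 2, 1,25D replicate 1 or 1,25D replicate 3 (adjusted p between 0.058 and 0.15), and the proliferation call without control replicate 1, control replicate 2 or 1,25D replicate 1 (0.091, 0.80 with the direction turned, and 0.28).

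The remaining lists were not called, and none of their members passed over all genes. Synaptic receptors had a median of -0.10 (adjusted p = 0.17), with Chrna4 and Htr2a, a serotonin receptor, at -0.40 ± 0.10 and -0.16 ± 0.11 (SE). Extracellular matrix genes had a median of -0.01 (adjusted p = 0.13), with Mmp2, a matrix metalloproteinase, at -0.46 ± 0.14 (SE). Inflammatory mediators had a median of -0.06 (adjusted p = 0.50), with Vcam1, an adhesion molecule, at -0.51 ± 0.28 (SE). The medians were 0.06 for cholesterol synthesis (adjusted p = 0.74), 0.03 for antioxidant and glutathione genes (0.82), 0.02 for calcium handling (0.82), -0.06 for immediate early genes (0.50), 0.03 for glycolysis and hypoxia (0.87), 0.00 for axon guidance and growth (0.88) and -0.03 for apoptosis (0.50). The mean had the other sign from the median for glycolysis and hypoxia and for axon guidance. Adjusted over the list alone with the block, Insig1, a regulator of sterol synthesis, passed as higher (1.29-fold) and Chrna4 as lower. Of these lists, camera called synaptic receptors lower and cholesterol synthesis higher without 1,25D replicate 3 (adjusted p = 0.023 and 3.3e-04), and extracellular matrix lower without 1,25D replicate 2 (0.018), all at the preset correlation. With an estimated correlation in the same omissions, the adjusted p = 0.79 for synaptic receptors and for cholesterol synthesis, and 0.49 for extracellular matrix.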

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

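The blocked repeats, the batch block, the subset of replicates 2 and 3, the omission of single arrays with an estimated correlation and the omission of genes with identical values were chosen after seeing the data. No gene was called lower in any setting except the blocked fits without replicate 1 or without replicate 3. The count of 5 genes became 18 with the replicate block, 3 after quantile normalisation (Fbln1, Grpr and S100g), 0 over all rows of the table (521 rows at an unadjusted p under 0.05), 0 with the unmoderated test (339 genes at an unadjusted p under 0.05), and 1 with replicates 2 and 3 only. Leaving out 1 array gave between 0 and 2. The other settings gave between 4 and 6. The blocked count of 18 became 10 after quantile normalisation, 40 with array weights, 1 over all rows, 0 with the unmoderated test and 5 with no replicate block. Without 1 pair it lay between 3 and 45. The unmoderated test has 4 residual degrees of freedom, or 2 with the block. For the other settings the cause was not tested. The replicate block changed no camera call of the 27 lists at the preset correlation. The 3 called lists became 0 with the correlation estimated per list, 0 with fry, and 0 under either with the replicate block, and between 1 and 5 without 1 array, and 0 whichever array was left out when the correlation was estimated. Interferon response had an adjusted p of 0.409 with the estimated correlation and 0.093 with fry (0.885 and 0.267 with the replicate block), and kept its call in every setting run at the preset correlation. Unfolded protein and amino acid stress had 0.432 and 0.71 (0.885 and 0.811 with the block), and between 0.00556 and 0.146 without 1 array. The estimated correlation without the block was -0.066 for interferon response and 0.007 for the stress list, both below the preset 0.01. Proliferation had 0.924 and 0.957 (0.885 and 0.811 with the block), 0.157 after quantile normalisation and 0.119 without the lowest 25% of genes. Without 1 array it lay between 3.98e-05 and 0.801, the highest with its direction turned (without control replicate 2). With the correlation estimated, all 3 of these lists had 0.914 without control replicate 1, 0.472 without control replicate 3 and 0.787 without 1,25D replicate 3. Without control replicate 2, 1,25D replicate 1 or 1,25D replicate 2, proliferation had 0.912 (its direction turned), 0.762 and 0.911, and the other lists 0.727, 0.601 and 0.488. At the preset correlation, neuron markers turned from lower to higher without 1,25D replicate 1, at 0.0345. Without 1 array, 4 other lists gained a call at that correlation in at least 1 setting. Their adjusted p ranged from 0.00202 to 0.948 for astrocyte markers, 0.0228 to 0.895 for synaptic receptors, 3.26e-04 to 0.56 for cholesterol synthesis and 0.0185 to 0.49 for extracellular matrix. A check planned on a single gene was not run. Median centring and quantile normalisation moved the median difference of all genes from 0.0074 to -0.0008 and 0.0011.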

Other observations

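The tests below on the ciliated cell list, on scaling, on coincidence of rounding, on bright genes with swapped labels and on list calls in splits that part all pairs, and the 3 added lists, were chosen after the result was seen. Beyond the genes called, the 39 genes at least 1.5-fold higher in each pair included 18 past the threshold with the block. Of the others, 5 are given here as values, chosen after they were seen. Dio2, the type 2 deiodinase that activates thyroid hormone, had a 1.81-fold higher mean, Lcat, which esterifies cholesterol in lipoproteins, 2.04-fold, Lpl, lipoprotein lipase, 2.46-fold, Car14, a carbonic anhydrase, 2.57-fold, and the small leucine-rich proteoglycan Prelp 1.85-fold. Their adjusted p-values with the block were 0.051, 0.051, 0.21, 0.11 and 0.057. A list of amino acid and related transporters, assembled after the data were seen and so not independent evidence, had 4 of 22 measured members called with the block (Slc7a3, Slc1a1, Slc43a3 and Slc6a11), all higher. Its camera adjusted p over the 3 added lists was 1.3e-05 (adjusted p = 0.087 with an estimated correlation). By fry it was 0.090, and 0.025 with the block. A list of smooth muscle and contractile genes, also added, had a median of -0.14 with 0 of 12 members called (camera adjusted p = 7.1e-04, and adjusted p = 0.070 with an estimated correlation). By fry its adjusted p was 0.069, and 0.025 with the block, again for a list chosen after the data were seen. The added list of ciliated cell genes had 0.55 and 0.61 by fry.

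Every gene called over all genes in the 6 arrays rose, in both fits; the blocked fits without replicate 1 and without replicate 3 called 2 and 5 genes lower. An array-wide scaling shift left in the tested values would need a median log2 difference over all genes near the size of the rises. The median was 0.0074, which argues against such a shift in these values. RMA had normalised the arrays beforehand, so this median cannot tell whether a shift was present before that step. Falls hidden by the floor stay open for genes not above the median control level, where 23 were at least 1.5-fold higher in each pair and 0 lower. Genes above that level have room to fall, so a floor would not hide falls there. Among them 16 were at least 1.5-fold higher in each pair and 0 lower. That passed the bound set beforehand (two-sided exact binomial p = 3.05e-05), but the bound takes genes as independent: with the labels of 1 pair swapped the counts were 0 higher and 0 lower for pair 1, 0 and 0 for pair 2, and 1 and 12 for pair 3, so a one-sided set also arose under 1 of the 3 other labellings. Activation by the treatment stays open too, untested here. The 10 splits of the 6 arrays, of which 1 (the real one) gave 5 genes and the highest other 0, and the 4 splits that part all pairs, of which 1 gave 18 and the highest other 0, are too few for a share under 0.05. For the lists, 7 of the 10 splits gave 3 or more calls at the preset correlation, and the highest other split gave 10, with control replicates 1 and 3 and 1,25D replicate 1 on one side. That split called several times the lists of the real one, a sign of structure among the arrays. It keeps the replicate 1 arrays together on that side and the replicate 2 arrays together on the other. Among the 4 splits that part all pairs, 1 (the real one) gave 3 lists and the highest other 2. These splits too are too few for a share under 0.05.

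The control and 1,25D arrays of replicate 1 held 1514 identical values, 4.26% of all rows. Coincidence of rounding is argued against by the other 14 pairs of arrays, which shared at most 26. A single library deposited under both labels is argued against by the 13 genes at least 2-fold higher in pairs 2 and 3, whose median difference in pair 1 was 1.90. If the replicate 1 arrays had been made or summarised apart from the others, they might stand further from them, yet in rows without a gene symbol both lay outside the other 4 on the same side in 27.8% of rows, against 21.1% for replicate 2 and 34.3% for replicate 3. The origin of the identical values stays open. They fix the pair 1 difference of 1094 genes at 0, and without those genes the counts were 6, and 22 with the block.

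Genes of motile cilia were among those with lower means in treated cultures, and the 26 listed members had a median difference of -0.28, with 0 called (camera adjusted p over the 3 added lists = 7.9e-06, and adjusted p = 0.29 with an estimated correlation). By pair the median was -0.85, -0.37 and 0.471, with 1, 0 and 24 of 26 genes higher in pairs 1, 2 and 3. The array medians were 8.93, 9.02 and 8.17 in controls 1 to 3 and 8.02, 8.59 and 8.45 in the treated cultures. The rise in pair 3 goes the other way from a treatment effect of the same direction in every pair. It rests on 1 control that lay below the other controls, as the fall in pair 1 rests on the treated array with the lowest median. Each pair difference holds 1 array per group, so such an effect stays open. Ciliated cell content that differs from culture to culture stays open too. On its first component lay 81.3% of the list's variance, more than in 99.4% of 1000 random lists matched on level (median 52.9%), which met the bound set for it. But the list was assembled after its genes were seen to be lower. Cholesterol synthesis, a list fixed in advance that names no cell type, had 82.2%, more than in 98.8% of its random lists.

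Among the rows without a gene symbol, 3 were at least 2-fold higher in each pair and 0 lower; they are not analysed further here.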
